A study of Eisenia fetida with 120 samples.

How the data were processed

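Expression was measured in RNA of homogenised whole earthworms (Eisenia fetida, adult) on 120 1-colour arrays of 1 custom design, with 1 worm per array. Each treatment began with 10 worms, all of which survived, and 5 of them were arrayed, per the labels. RNA was extracted on silica columns, its amount and quality were measured, and Cy3-labelled cRNA was made from 0.5 ug of RNA, per the labels' protocols. The array intensities were extracted with Agilent Feature Extraction version 10.7.3.1, per the file headers, while the design text names version 9.1.3, so the version in the headers is taken as the one that wrote the files. The processed intensity of each spot, background-subtracted by that software, and its quality flags are the deposited values used, per the file headers. The authors also deposited a table of log2 values without stating how it was made. Set against the scanner files, each of its columns was an exact linear function of that array's log2 processed intensity (r = 1), with a median of 0 and a slope between 0.949 and 1.24 that differed between arrays. The table is thus on a log2 scale, centred per array and rescaled by a factor whose origin is unknown.

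The 15208 probes (8115 with the ID prefix TA1, 7093 with TA2) are described as unknown in the files, and no reference came with the series. No probe could be given a gene name, and the gene lists fixed beforehand could not be tested. The dose is given as ppm in the titles, as mg per kg and mg per g in the design text and as mg per g in the source names. The ppm of the titles was used, and no result depends on the unit, since only ratios of doses enter the tests.

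Each spot's processed intensity was taken to log2 and the array's 75th percentile was subtracted. The 536 control spots were left out, and 776 spots marked as outliers were set missing. A probe was tested if it was well above background on at least 4 of the 5 arrays of at least 1 group, which kept 15203 probes. Between 0 and 87 probes per array were marked as outliers, and none was saturated. The median processed intensity per array ran from 367.3 to 3023.8, and the share of probes well above background from 95.8% to 99.9%. The number of arrays limits the precision. Within groups, arrays correlated with r between 0.753 and 0.938 (median 0.895, across probes), and the highest r of any pair of arrays was 0.943.

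The 24 groups of 5 worms come from the labels. The arrays lie on 15 slides of 8 arrays with 7 or 8 groups each, and the slides were scanned on 2 days (48 and 72 arrays), with all 24 groups on both. Every comparison came from 1 limma model with a mean per group and slide as a fixed block over all 120 arrays, followed by eBayes and Benjamini-Hochberg adjustment at 0.05. It left 82 residual degrees of freedom (prior 2.22) and a median residual SD of 0.379 log2. The comparisons were blank against T0 control in each set, the 3 T0 controls by an F test, solvent against blank control, the HMX trend over solvent control and 5 doses in steps of a doubling, each dose against the solvent control (5 contrasts adjusted together), and an F test of equal trends at the 3 days. An F test of equal soil changes in the 3 sets, and the lists of probes changed in all 3, were added after the data were examined. Changes along the trend are the slope times 5. P-values are from worms as replicates. They rest on 1 spread between worms per probe, pooled over the 24 groups of the 3 sets.

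The nominal dose was predicted by kernel ridge regression (linear kernel, penalty equal to the mean of the training kernel's diagonal) from all tested probes without missing values, leaving out 1 slide at a time. The error was tested with 100000 permutations of the doses over the 30 worms of a day.

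The rule for named probes, fixed before the data were examined, takes the 2 that rose most and the 2 that fell most among those past the threshold in each comparison, or the 2 with the highest F, or where none passed the 2 with the smallest p. For each dose against solvent it was applied over the doses of a day, and fewer are named where fewer passed or a probe led at several doses. Where a probe was not well above background on any array of a group, its fold is given as a bound against the lowest signal among probes well above background on those arrays.

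The procedure was tested on simulated data with the real spread (14549 probes). For the day 28 trend it recovered 24%, 84%, 86% and 80% of probes changed by 0.5, 1, 1.5 and 2 log2, and 4.2% of its calls were unchanged probes. For blank against T0 control in the 28-day set it recovered 14%, 58%, 64% and 80%, with 6.9% of calls unchanged. The simulated noise was normal and drawn separately for each probe and array. It held no probes that move together or switch between 2 levels, as some real probes do, so these shares may not hold for the real arrays. Alternatives covered quantile normalisation, normexp background (offset 50), the filter, the slide block left out or random, replicate number as a block, array weights, the authors' values, the arrays of 1 set alone, pooled blank and solvent controls, doses in ppm, the trend without the solvent control, and each worm left out in turn. Scan day, arrays with under 98% of probes well above background, 1 set without a slide block, and the leading axis of variation between worms were added after the data were examined. R (4.3.3), limma (3.58.1), statmod (1.5.0) and data.table (1.17.8) were used.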

Results

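Transcript levels were measured in whole adult earthworms (Eisenia fetida) kept in soil spiked with HMX, a nitramine explosive used in munitions. The series holds 120 arrays, each from the RNA of 1 worm. They form 3 exposure sets that ended at day 4, day 14 and day 28, and each set holds 8 groups of 5 worms. Before the exposure the worms lived in moistened peat, per the labels. A T0 control was taken at day 0, a blank control stayed in unspiked soil, a solvent control stayed in soil treated with the solvent acetone alone, and 5 groups received HMX at 8, 16, 32, 64 or 128 ppm. The labels give the dose unit in conflicting ways, as ppm in the sample titles and as mg per kg and mg per g in the design text, so the titles' ppm is used throughout. Each array carries 15208 probes of 60 nucleotides, and every probe targets a different transcript. No file pairs the probes with genes, so transcripts are named by probe ID, with the sequence of a few of them. The median processed signal per array ran from 367.3 to 3023.8 with a median of 1669, and between 95.8% and 99.9% of the probes were well above background. Levels are log2 values relative to the 75th percentile of the same array. Fitted changes are adjusted for slide, and a change along the dose is 5 times the fitted slope per doubling, so both can differ from the difference of 2 group means. The number of arrays limits the precision.

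In each set, more transcripts differed between T0 and the blank control in unspiked soil than followed the HMX dose. Blank control against T0 control sets worms after a stay in unspiked soil against worms taken at day 0, so the soil, the time and the transfer are not separated, and the difference is called the soil change below only for short. The probe TA2-008489 (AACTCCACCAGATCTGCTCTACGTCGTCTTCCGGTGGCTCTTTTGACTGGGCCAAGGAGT) stood at -4.32 ± 0.90 (SD, n = 5) in T0 of the 28-day set and at 1.78 ± 0.86 (SD, n = 5) in the blank control after 28 days. This was a rise of 5.96 ± 0.88 (SE), or 62.3-fold, with an adjusted p of 3.81e-07, and all 5 blank worms lay above all 5 T0 worms. The solvent control and the 5 HMX groups of that set had similar means, from 1.66 to 2.07. In the 14-day set the same probe rose 37.3-fold (log2 5.22 ± 0.87 SE, adjusted p = 6.54e-05), and in the 4-day set its change of 1.19 ± 0.86 (SE) did not pass the test (adjusted p = 0.43). The probe TA2-043894 (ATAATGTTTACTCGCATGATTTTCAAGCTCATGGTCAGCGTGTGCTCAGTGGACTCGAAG) went the other way. It was at 0.92 ± 1.07 (SD, n = 5) in T0 of the 28-day set and at -4.93 ± 2.33 (SD, n = 5) in the blank control, a 45.5-fold fall (adjusted p = 4.83e-08). Its change of -3.11 ± 0.74 (SE) in the 14-day set also passed (adjusted p = 0.00628), and its change of -1.50 ± 0.73 (SE) in the 4-day set did not (adjusted p = 0.195).

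**Figure D1:**
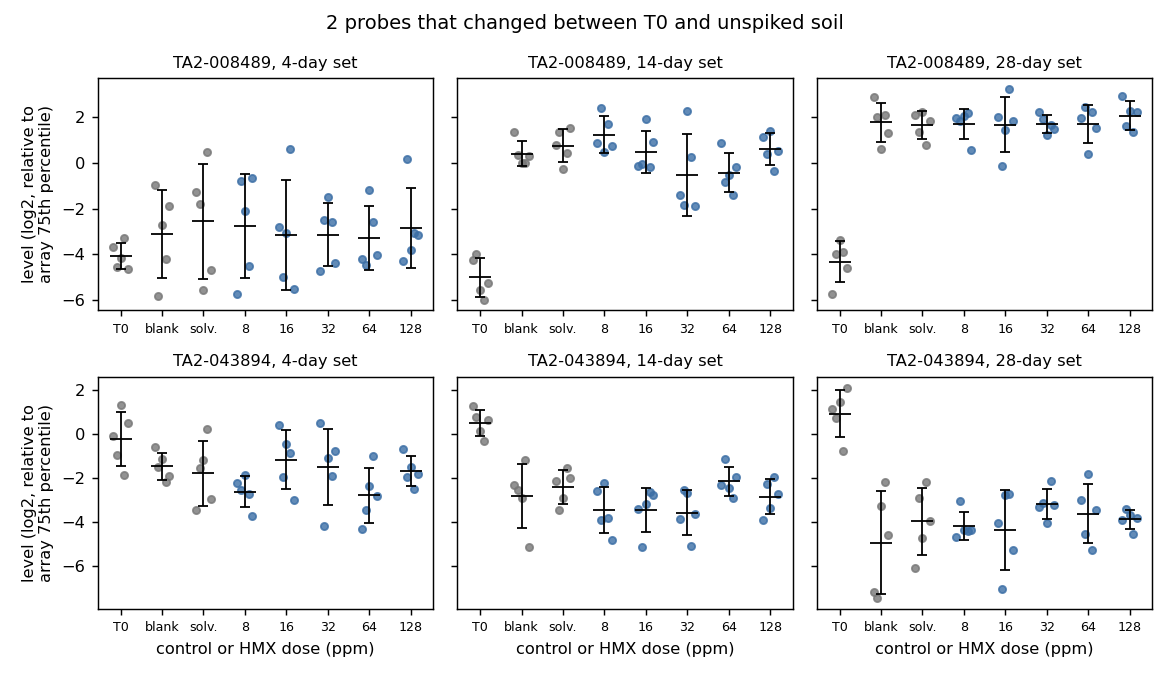
Level (log2 relative to the array's 75th percentile) of TA2-008489 and TA2-043894 in each of the 120 worms, by exposure set, control and HMX dose in ppm; points are worms, bars the group mean and SD. In the 28-day set TA2-008489 was at -4.32 in T0 and between 1.66 and 2.07 in the groups kept in soil, and TA2-043894 fell from 0.92 to -4.93 in the blank control.

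Between T0 and the blank control of day 4, 1349 of 15203 probes changed, of which 720 rose and 629 fell. The median size was 0.71 log2 among those that rose and 0.91 log2 among those that fell. TA1-048166 rose 19.9-fold, from -1.81 ± 0.27 to 2.18 ± 0.76 (SD, n = 5 each), and TA1-133892 rose 19.6-fold (log2 4.29 ± 0.67 SE). TA2-203815 fell 16.7-fold, and TA2-135639 fell 13.4-fold, from -2.51 ± 0.54 to -5.93 ± 1.15 (SD, n = 5 each). After 14 days 376 probes had risen and 260 had fallen. Next to TA2-008489, TA2-121982 rose 8-fold (log2 3.00 ± 0.81 SE). TA2-203815 fell 21.5-fold and TA1-070536 fell 12.4-fold. TA2-203815 was well above background on all 5 T0 arrays and on 3 of the 5 blank arrays of that set.

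After 28 days 1115 probes had risen and 810 had fallen, with median sizes of 0.72 and 1.10 log2. TA2-211628 rose 24.6-fold, from -3.69 ± 3.41 to 1.08 ± 1.14 (SD, n = 5 each), and was well above background on 4 of the 5 T0 arrays, so the size rests partly on an unmeasured value. The lowest fitted value belonged to TA1-197475, which was well above background in 4 of 5 T0 worms and in none of the 5 blank worms. Its T0 mean was 36.3-fold above the background bound of the blank arrays, with an adjusted p of 0.0459 in limma's test. That mean includes a T0 worm not well above background, so the fold is not a lower limit. For such a probe the bound is the lowest signal among probes well above background on the dim arrays. The call on TA1-197475 was lost in 8 of 10 fits that left out 1 worm, with quantile normalisation, normexp background, array weights, the authors' values or that set's arrays alone, within each scan day, and without the arrays on which under 98% of probes were well above background.

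The soil changes of the 3 sets can be compared directly, because each set had its own T0 and blank worms. Of the probes that changed after 14 and 28 days, 222 rose in both sets and 155 fell in both, where independent lists would share 27.6 and 13.9. None went in opposite directions. The 4-day and 14-day sets shared 49 risen and 92 fallen probes (17.8 and 10.8 for independent lists). Of the probes changed in the 4-day set, 14.9% of those that rose also rose in the 28-day set and 21.8% of those that fell also fell there (7.33% and 5.33% for independent lists). Between those 2 sets, 13 probes rose at day 4 and fell at day 28, and 20 did the reverse. In all 3 sets 38 probes rose and 63 fell, where independent lists would give 1.31 and 0.57. Among those that rose were TA2-155264, with log2 changes of 2.43, 2.53 and 3.27 at days 4, 14 and 28, and TA2-182267, with 1.62, 2.77 and 2.73. Among those that fell were TA2-000525 (-2.21, -2.01 and -4.26) and TA2-130995 (-1.95, -2.13 and -4.14). This comparison of lists was added after the data had been examined. All the lists came from 1 fit with 1 spread per probe, so probes with a small spread pass more readily in every set. The numbers for independent lists may thus be too low as a baseline. A shared spread alone favours neither the same nor the opposite direction.

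**Figure D2:**
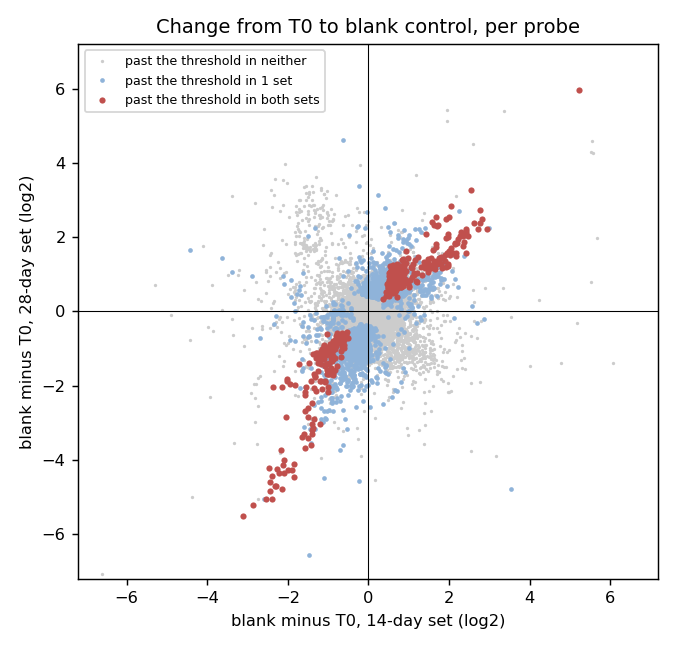
Log2 change from T0 to blank control in the 14-day set (horizontal) against the 28-day set (vertical), 1 point per probe; red points passed the adjusted p of 0.05 in both sets and blue points in 1 set. The 222 probes that rose in both lie at the upper right, the 155 that fell in both at the lower left, and none lies in the other corners.

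The size of the soil change itself differed between the sets for 520 probes (F test with 2 degrees of freedom in limma, added after the data had been examined). TA2-135639 had the highest F (31.7, adjusted p = 8.3e-07). It fell by 3.75 in the 4-day set, and its changes in the 14-day and 28-day sets did not pass (adjusted p = 0.206 and 0.055). Its mean was -2.51, -4.87 and -4.62 in T0 and -5.93, -6.04 and -3.63 in the blank control of the 4-day, 14-day and 28-day sets (n = 5 each). The 4-day and 14-day sets thus differed mainly in T0. TA1-155307 (F = 23.2) fell by 0.79 ± 0.22 (SE) in the 4-day set and rose by 0.70 ± 0.22 and 1.29 ± 0.22 (SE) in the 14-day and 28-day sets. The sets differ in the worms as well as in the length of the stay.

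The tests of the soil changes used limma with Benjamini-Hochberg adjustment, and with scan day in place of slide as the block the counts were 1393, 773 and 1939 probes at days 4, 14 and 28. Within the arrays of scan day 1 they were 20, 10 and 425, and within scan day 2 they were 158, 66 and 269, from fewer worms. With each set's arrays alone they were 493, 165 and 1033, with normexp background 750, 464 and 2503, and with array weights 2795, 974 and 2208. Without the arrays on which under 98% of probes were well above background they were 1353, 539 and 920. The 520 probes became 0 and 4 within the scan days, and the 101 probes shared by all sets became 0 and 4. TA2-008489 at day 28 passed within both scan days, with changes of 6.76 and 6.02. Without blank replicate 5 the day 4 count was 574, without T0 replicate 3 it was 813, without T0 replicate 6 it was 820 and without blank replicate 4 it was 881; at day 14 it was 352 without T0 replicate 3 and 359 without T0 replicate 4.

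**Figure D3:**
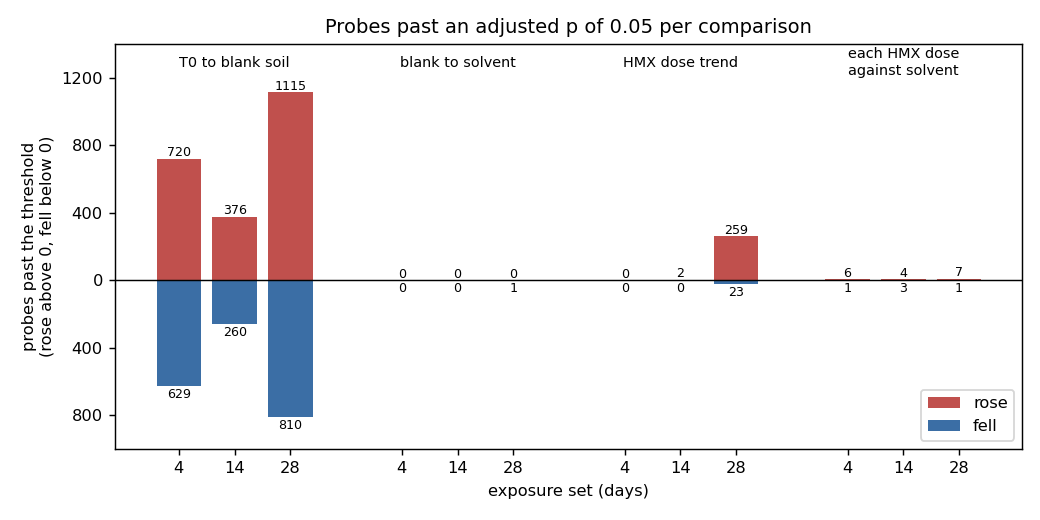
Number of probes past an adjusted p of 0.05 in each comparison and exposure set, with risen probes drawn above 0 and fallen probes below. The counts were 1349, 636 and 1925 probes from T0 to blank control, 0, 0 and 1 from blank to solvent control, and 0, 2 and 282 for the HMX dose trend.

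The 3 T0 controls were taken at day 0, and their comparison shows how far the worms of the sets differed at the start. The probe TA2-040077 (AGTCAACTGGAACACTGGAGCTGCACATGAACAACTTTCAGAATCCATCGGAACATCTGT) was at -1.10 ± 0.81 in T0 of the 4-day set, at -0.26 ± 0.72 in that of the 14-day set and at 2.98 ± 0.17 in that of the 28-day set (SD, n = 5 each). TA1-236535 had nearly the same levels, -0.80 ± 0.71, -0.25 ± 0.83 and 2.86 ± 0.30 (SD, n = 5 each). The fitted differences between the 28-day and 4-day sets were 4.00 ± 0.45 and 3.52 ± 0.41 (SE). In all, 78 probes differed among the 3 T0 controls by limma's F test, and F was 43.8 for TA2-040077 and 42.4 for TA1-236535 (adjusted p = 1.38e-09 for each). In pairs of sets, 79 probes differed between the 28-day and 4-day sets, 20 between the 14-day and 4-day sets and 4 between the 28-day and 14-day sets. With scan day as the block 100 probes differed, against 1 and 2 within the scan days. The count was 33, 36 or 45 without replicate 3, 2 or 5 of the 4-day T0 and 49 without replicate 4 of the 14-day T0.

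The solvent control against the blank control asks whether the carrier alone changed the worms. TA2-045333 was lower in the solvent control of the 28-day set, at -1.96 ± 0.70 against -0.72 ± 0.07 (SD, n = 5 each) in the blank control, and it was the only probe of the 3 sets to pass (log2 -1.21 ± 0.24 SE, adjusted p = 0.0487). All 5 solvent worms lay below all 5 blank worms. At day 4 no probe passed limma's test, with 444 at an unadjusted p under 0.05. The probes with the smallest p there, TA1-040663 (0.76 ± 0.20 SE) and TA2-033124 (1.01 ± 0.28 SE), had an adjusted p of 1. At day 14 none passed, with 429 at an unadjusted p under 0.05, and the smallest p belonged to TA2-178657 (1.58 ± 0.38 SE) and TA2-040077 (-1.73 ± 0.43 SE), again with an adjusted p of 1. The call on TA2-045333 was lost in 8 of 10 fits that left out 1 worm, under 8 other settings and within each scan day (adjusted p = 1 in both).

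The dose series asks how transcripts followed the amount of HMX, from the solvent control over the 5 doses in steps of a doubling. At day 28 the probe TA1-161768 (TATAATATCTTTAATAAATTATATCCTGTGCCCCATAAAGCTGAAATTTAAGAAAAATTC) was at 2.74 ± 0.70 in the solvent control, 2.75 ± 0.97 at 8 ppm, 2.65 ± 0.89 at 16 ppm, 1.22 ± 2.48 at 32 ppm, -0.58 ± 2.58 at 64 ppm and -1.79 ± 1.06 at 128 ppm (SD, n = 5 each). All 5 worms at 128 ppm lay below all 5 of the solvent control. Its fitted fall from solvent to 128 ppm, 5 times the slope, was 5.67 ± 0.94 (SE) on the log2 scale, or 50.9-fold, with an adjusted p of 0.000217, and the call was lost in 0 of 30 fits that left out 1 worm. The blank control was at 2.98 ± 0.76 and T0 at 2.15 ± 1.23 (SD, n = 5 each). In the 4-day set T0 was at 0.864 ± 2.438 and the blank control at 3.195 ± 0.713 (SD, n = 5 each). In the 14-day set T0 was at 2.598 ± 0.755 and the blank control at 2.008 ± 2.354 (SD, n = 5 each). Some groups without HMX thus varied as widely as those at 32 and 64 ppm, so the fitted fall need not be an even one within each worm.

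Several probes at day 28 had levels that switched between worms and not in even steps. TA1-160389 was well above background in 1 of 5 solvent worms, in 3 at 8 ppm, 4 at 16 ppm, 3 at 32 ppm and in all 5 at 64 and at 128 ppm, but also in 4 of 5 worms of the blank control and 4 of 5 of T0, so the solvent control was the group that stood apart. Its trend passed (adjusted p = 0.0444), but its size is not given, since 4 of the 5 solvent signals were not well above background, and the call was lost in 18 of 30 fits that left out 1 worm and with pooled controls (adjusted p = 0.112). TA1-037207 rose by 5.31 ± 1.45 (SE, adjusted p = 0.0297), from -2.35 ± 2.94 in the solvent control to 1.66 ± 1.16 at 128 ppm (SD, n = 5 each). Worms without HMX varied widely too, with -1.265 ± 3.499 in the blank control and 0.055 ± 3.048 in T0 (SD, n = 5 each). TA1-156311 was well above background in all 5 solvent worms and in none of the 5 worms at 128 ppm, at least 48.7-fold lower there, with an adjusted p of 0.0106 for its trend. At 8, 16, 32 and 64 ppm it was so in 4, 3, 4 and 3 of 5 worms, in the blank control in 3 of 5 and in T0 in 4 of 5, so worms without HMX also lacked the signal at times. The call on TA1-037207 was lost in 6 of 30 fits that left out 1 worm, with no slide block (adjusted p = 0.101), with doses in ppm (0.112), without the solvent control (0.309) and with the leading axis of variation between worms as a covariate (0.15). It was also lost with that set's arrays alone (0.253), without the arrays under 98% well above background (0.0537) and within each scan day. The calls on TA1-160389, TA1-037207 and TA1-156311 ended with normexp background correction (adjusted p = 0.18, 0.0556 and 0.18) and with scan day as the block (0.0671, 0.052 and 0.0611). That on TA1-156311 also ended without the solvent control (0.237), with no slide block (0.0722), the replicate block (0.0514), that set's arrays alone (0.619) and the axis covariate (0.11). That on TA1-160389 also ended with quantile normalisation (0.0538), no slide block (0.0892), the replicate block (0.112) and the authors' values (0.061).

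**Figure D4:**
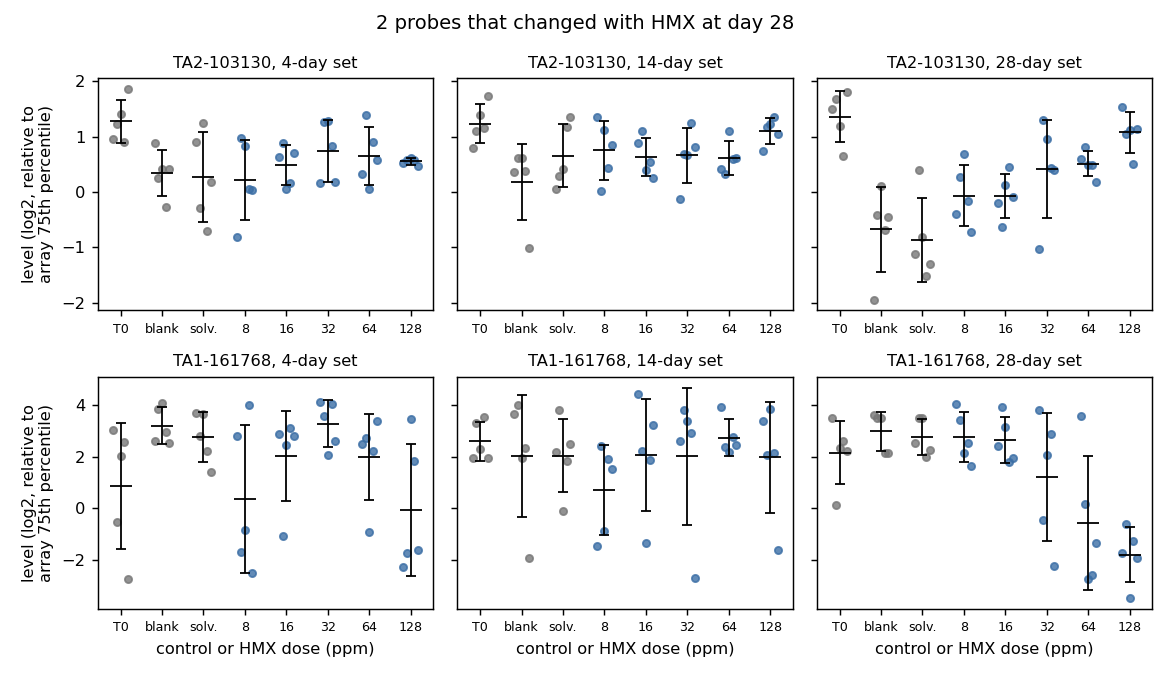
Level (log2 relative to the array's 75th percentile) of TA2-103130 and TA1-161768 in each worm, by exposure set, control and HMX dose in ppm; points are worms, bars the group mean and SD. At day 28 TA2-103130 went from -0.87 in the solvent control to 1.08 at 128 ppm, near its T0 level of 1.36, and TA1-161768 went from 2.74 to -1.79.

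In all, 282 probes followed the dose at day 28, and 259 of them rose. The median fitted rise from solvent to 128 ppm was 1.97-fold, and the 23 probes that fell did so by a median of 2.38-fold. The mean level of the 259 risen probes was 0.56 ± 0.59 in the solvent control, 0.89 ± 0.35 at 8 ppm, 0.90 ± 0.30 at 16 ppm, 1.22 ± 0.40 at 32 ppm, 1.41 ± 0.21 at 64 ppm and 1.61 ± 0.24 at 128 ppm (SD, n = 5 each). Solvent replicate 2 was at 1.544, near the mean at 128 ppm, and the other 4 solvent worms lay between -0.031 and 0.528. In the untreated worms the mean was 1.27 ± 0.30 in T0 and 0.54 ± 0.31 in the blank control (SD, n = 5 each). Of these 259 probes, 114 also fell from T0 to the blank control of that set and 6 rose. At day 14 TA2-046788 rose by 1.31 ± 0.27 (SE, adjusted p = 0.0425) and TA2-182212 by 1.18 ± 0.23 (SE, adjusted p = 0.0338), and no other probe passed, with 1087 at an unadjusted p under 0.05. TA2-046788 was at -2.19 in the solvent control, -0.82, -1.50, -1.18, -0.42 and -0.79 from 8 to 128 ppm and -1.03 in the blank control, and TA2-182212 was at -0.71, then -0.17, -0.46, -0.16, 0.37 and 0.52, and 0.17 in the blank control (means, n = 5 each). The solvent control was thus the lowest of these groups for both, and the doses gave no steady rise. At day 4 no probe passed limma's test, with 926 at an unadjusted p under 0.05. The smallest p there belonged to TA1-209959 (1.68 ± 0.34 SE, adjusted p = 0.0742) and TA2-007287 (-0.69 ± 0.16 SE, adjusted p = 0.286).

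The day 28 count was 248 with scan day as the block, 191 within scan day 2 and 0 within scan day 1, where TA1-161768 changed by -6.14 (adjusted p = 0.857). The count was 2 from the arrays of that set alone (62 with no slide block), 31 with the leading axis of variation between worms as a covariate, 121 without the arrays under 98% well above background, 186 with normexp background, 533 with pooled controls, 834 with array weights, 56 without the solvent control, 131, 182 and 699 without solvent replicate 4, 3 or 2, and 166 without 64 ppm replicate 5. At day 14 neither probe passed within a scan day, without the solvent control or with pooled controls (adjusted p = 0.0859 and 0.168), and 26 of 30 fits that left out 1 worm moved the count of 2, to between 0 and 7.

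Each HMX dose was also set against the solvent control of its day. At day 28 the probe TA2-103130 (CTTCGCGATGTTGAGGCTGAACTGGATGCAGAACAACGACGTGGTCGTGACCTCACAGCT) was higher at 128 ppm by 1.88 ± 0.35 (SE), or 3.68-fold, with an adjusted p of 0.0264. Its level was -0.87 ± 0.76 in the solvent control and 1.08 ± 0.37 at 128 ppm, against -0.68 ± 0.77 in the blank control and 1.36 ± 0.46 in T0 (SD, n = 5 each). All 5 worms at 128 ppm lay above all 5 of the solvent control. From T0 to blank control the same probe fell by 1.00, 1.09 and 1.89 in the 3 sets (adjusted p = 0.045, 0.0493 and 4.17e-05). TA2-005491 had a similar course, from -0.98 ± 0.69 in the solvent control to 0.78 ± 0.34 at 128 ppm (SD, n = 5 each), a 3.33-fold rise (adjusted p = 0.0424). TA2-139232 was 3.9-fold lower at 32 ppm than in the solvent control (adjusted p = 0.0123), with means of 1.39 in the solvent control, 0.41 in the blank control and -0.48 at 32 ppm (n = 5 each). The calls on TA2-103130, TA2-005491 and TA2-139232 were lost in 6, 11 and 3 of 30 fits that left out 1 worm, and all 3 with the arrays of that set alone and within scan day 1. That on TA2-005491 also ended with quantile normalisation (adjusted p = 0.0509), normexp background (0.0965), the authors' values (0.0611) and the leading axis of variation between worms as a covariate (0.136), and that on TA2-103130 with that covariate (0.0923).

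At day 14 TA2-040077 was 4.69-fold and TA1-236535 4.02-fold higher at 64 ppm than in the solvent control, TA2-136102 was 4.42-fold lower at 64 ppm, and TA1-171375 was 2.65-fold lower at 16 ppm (adjusted p = 0.0374 for each). TA2-040077 was at 1.01 ± 1.07 in that solvent control, at 2.73 ± 0.49 in the blank control and at 3.27 ± 0.31 at 64 ppm (SD, n = 5 each). TA2-136102 was at -0.07 in the solvent control, -1.61 in the blank control and -2.10 at 64 ppm, and TA1-171375 at 0.80, 0.24 and, at 16 ppm, -0.70 (means, n = 5 each). With pooled controls the changes of TA2-040077, TA1-236535, TA2-136102 and TA1-171375 were 1.265, 1.197, -1.414 and -1.25 (adjusted p = 0.637, 0.573, 0.335 and 0.0784). None of the 4 probes passed with pooled controls, without the arrays under 98% well above background (0.0613 for each), within either scan day or with the arrays of that set and slide as the block, and TA2-040077, TA1-236535 and TA2-136102 did not pass with the leading axis of variation between worms as a covariate (0.0793 for each). At day 4 TA2-040077 was 4.48-fold higher at 32 ppm, TA1-209959 4.45-fold higher at 128 ppm and TA2-136102 4.27-fold lower at 16 ppm (adjusted p = 0.0498 for each). There TA2-040077 was at 1.12 ± 1.04 in the solvent control, 2.23 ± 0.71 in the blank control and 3.26 ± 0.84 at 32 ppm (SD, n = 5 each). The calls on TA2-040077, TA1-209959 and TA2-136102 were lost in 16, 14 and 19 of 30 fits that left out 1 worm, and all 3 ended with quantile normalisation, normexp background, the replicate block, that set's arrays alone and within either scan day. With pooled controls TA2-040077 changed by 1.63 (adjusted p = 0.168), and within scan day 2 by 1.328 (adjusted p = 1).

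These tests, adjusted over all probes and 5 doses of a day, called 7 probes at day 4, 7 at day 14 and 8 at day 28, of which 6, 4 and 7 were higher. With scan day as the block the counts were 11, 11 and 47, within scan day 1 they were 3, 1 and 0, and within scan day 2 they were 1, 0 and 25. With array weights they were 42, 21 and 950, with pooled controls 18, 0 and 337, and with each set's arrays alone 0 at every day. They rested on few worms: leaving out 1 worm moved them to between 0 and 14, between 0 and 9, and between 0 and 324, the last of these without solvent replicate 2. TA2-103130 was higher at 128 ppm of day 28 by 1.243 within scan day 1 (adjusted p = 1) and by 2.209 within scan day 2 (adjusted p = 0.0233).

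Whether the dose trend differed between days was tested directly. TA1-161768 had a slope of -1.13 ± 0.19 (SE) per doubling at day 28, against -0.24 ± 0.18 at day 4 and 0.26 ± 0.18 at day 14 (SE each). TA2-139232 (F = 16.7, adjusted p = 0.0115) had slopes of -0.24 ± 0.06 at day 28, 0.25 ± 0.06 at day 14 and 0.03 ± 0.06 at day 4 (SE each). Among the groups kept in soil its solvent control was the extreme one at both later days, with a mean of 1.39 against 0.41 in the blank control and -0.48 to 0.53 at the doses of day 28, and of -0.65 against 0.15 and 0.18 to 1.17 at day 14 (n = 5 each), and without the solvent control its adjusted p was 0.683. TA2-040077 (F = 14.3, adjusted p = 0.0243) had slopes of 0.23, 0.34 and -0.19 at days 4, 14 and 28, and TA1-236535 had slopes of 0.20, 0.30 and -0.17. These 4 probes were the ones past limma's F test with 2 degrees of freedom, and TA1-161768 (F = 14.2, adjusted p = 0.0243) and TA1-236535 (F = 13.4, adjusted p = 0.0341) are named after their values were seen. The 282 calls at day 28 and 0 at day 4 are thus not shown to differ for the other probes. Across all probes, which are not independent replicates, the slopes of days 14 and 28 correlated with r = 0.39 (Spearman's rho = 0.30), those of days 4 and 14 with r = 0.08 and those of days 4 and 28 with r = 0.03. The count was 7 with scan day as the block and 0 within each scan day, 0 without the solvent control or on a ppm scale, 0 without solvent replicate 8 of day 14 and 65 without solvent replicate 2 of day 28.

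The series title names the prediction of HMX bioavailability by regression on expression. Measured body burdens are not among the labels, so the nominal dose in doublings was predicted for the worms of a left-out slide from the other slides. At day 28 the mean predicted step rose from 2.22 ± 0.74 for the solvent control to 2.71 ± 0.57 for 128 ppm (SD, n = 5 each), where the nominal steps run from 0 to 5. The mean absolute error was 1.38 doublings, against 1.53 for a prediction by the mean of the training worms (one-sided permutation p = 0.024, adjusted over the 3 days p = 0.0721, 30 worms). At day 14 the mean prediction went from 2.16 ± 0.41 for the solvent control to 2.87 ± 0.23 for 64 ppm and 2.49 ± 0.26 for 128 ppm (SD, n = 5 each). The error there was 1.41 doublings against 1.52 (permutation p = 0.0499, adjusted p = 0.0749). At day 4 the error of 1.57 doublings lay above the 1.51 of the mean (permutation p = 0.513, adjusted p = 0.513). No day passed after adjustment. Days 14 and 28 both did with the authors' values (adjusted p = 0.0348 and 0.0446), with slide means removed (0.0225 and 0.0183) and with a penalty 10 times smaller (0.034 for each).

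**Figure D5:**
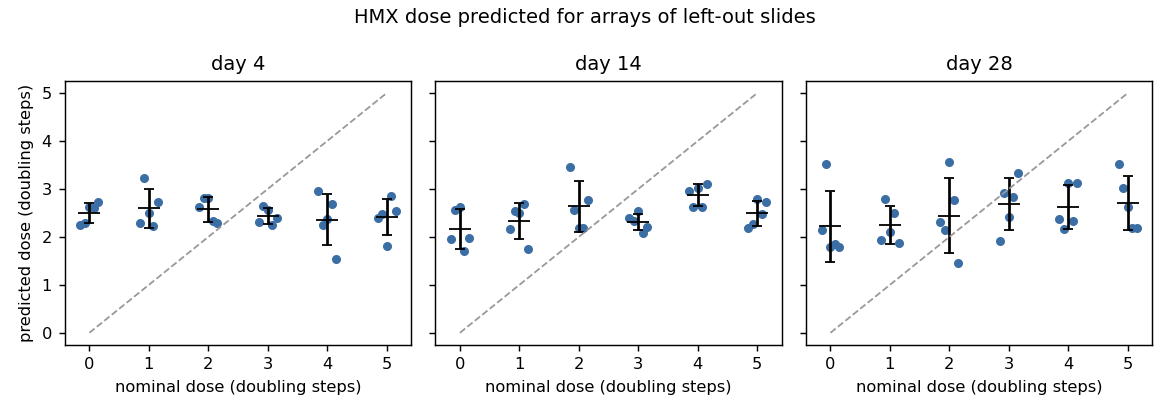
Predicted against nominal HMX dose, both in doubling steps (0 is the solvent control, 5 is 128 ppm), for the 30 worms of each day, each predicted from the slides that did not hold it; bars give the group mean and SD and the dashed line equality. The means stay between 2.16 and 2.87 at each day, and at day 28 they go from 2.22 for the solvent control to 2.71 for 128 ppm.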

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

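The test of the soil change between sets and the checks for single worms far from their group were chosen after the results were seen; the test of the dose trend between days was planned. The dose trend differed between the 3 days for 4 probes, with F = 16.7 for TA2-139232 and F = 14.3 for TA2-040077. TA2-040077 was also the probe that differed most among the T0 controls of the sets, before any exposure. The soil change differed between the 3 sets for 520 probes, with F = 31.7 for TA2-135639 and F = 23.2 for TA1-155307.

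Single worms stood apart from the other 4 of their group in probes that the report names. For TA1-160389, which is on in some worms and off in others, 1 solvent worm of day 28 was at 1.45 where the others lay between -10.69 and -9.71 (not well above background), and 1 worm at 16 ppm was at -8.51 where the others lay between -0.06 and 0.54. For TA1-156311, 1 solvent worm of day 28 was at -5.72 (others -2.22 to -1.69). TA2-040077 was at 1.80 in 1 worm at 32 ppm of day 4 (others 3.45 to 3.94), at 1.86 in 1 blank worm of day 14 (others 2.84 to 3.02) and at 3.28 in 1 T0 worm of the 28-day set (others 2.83 to 2.94). For TA2-005491, 1 worm at 32 ppm of day 28 was at -1.43 (others 0.35 to 0.99). TA2-008489 was at 1.36 in 1 blank worm of day 14 (others -0.01 to 0.34), and TA1-155307 at -1.0 in 1 T0 worm of the 14-day set (others -0.26 to 0.01). These are 9 of 169 groups of values, and chance marks about 1 in 20.

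For array brightness and for the percentage of probes well above background, chance would mark 1.2 of 24 groups each. Both had more such values, but the excess for brightness rests on 3 groups and was not tested. Brightness, the 75th percentile of log2 signal, stood apart in 3 of 24 groups. The values were 10.19 for 1 array at 32 ppm of day 4 (others 12.01 to 12.75), 11.82 for 1 blank array of day 14 (others 12.32 to 12.47) and 12.90 for 1 array at 8 ppm of day 28 (others 12.16 to 12.36). The percentage of probes well above background stood apart in 8 of 24 groups, always as 1 low array. It was 97.26 at 8 ppm and 98.36 at 32 ppm of day 4, and 97.13 at 16 ppm, 99.19 at 32 ppm and 97.62 in T0 of the 14-day set. In the 28-day set it was 97.54 in the blank control, 98.38 in the solvent control and 97.00 in T0. The other arrays of these groups lay between 99.11 and 99.74. The 8 low arrays also had the highest score of their groups on the axis of the 500-probe block described below. Their scores ran from 11.54 at 32 ppm of day 14 to 121.99 in the blank control of day 28. A low percentage is thus not told apart from a low block, and leaving out arrays under 98% also takes out worms with that block low.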

How the results depend on the processing

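Leaving out each worm, the block by replicate number and most other settings were planned before the data were examined; scan day, arrays under 98% of probes well above background, the axis of variation between worms, 1 set without a slide block, and all settings of the soil difference and of the probes shared by all sets were chosen afterwards. No result reversed. The solvent counts at days 4 and 14 stayed at 0 under all 16 alternatives. Of the named probes' values under all alternatives, 1303 kept their side of the threshold, 344 fell below it and 12 rose past it. The cause of the changes listed here was not tested. The unfiltered setting adds 5 probes and tests nothing. The gene lists, with their alternative for the correlation between genes, were not run, since no probe has a gene name. Signal over background limits the on and off probes, whose lower level is unmeasured.

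The HMX trend at day 4 (0 probes) became 1 with quantile normalisation, no slide block, a random slide block, array weights, the authors' table, pooled controls, doses in ppm, scan day as the block and the axis covariate. The trend at day 14 (2) became 5 with quantile normalisation, no slide block or scan day as the block, 7 with a random slide block, 50 with array weights, 8 with the authors' table, 13 with pooled controls and 1 in ppm. It became 0 with its own set's arrays alone, with or without the slide block, without the solvent control, within either scan day and with the axis covariate. The trend at day 28 (282) became 186 with normexp, 834 with array weights, 2 with its own set alone, 62 with that set and no slide block, 533 with pooled controls, 56 without the solvent control, 0 within scan day 1, 121 without the low arrays and 31 with the axis covariate.

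For each dose at day 4 (7), the count was 0 with quantile normalisation, its own set alone (with or without the slide block) and without the low arrays, 1 with normexp, the authors' table or scan day 2 alone, 3 in scan day 1, 11 with a random slide block or scan day as the block, 42 with array weights and 18 with pooled controls. At day 14 (7) it was 11 with a random slide block or scan day as the block, 21 with array weights, 0 with its own set alone, pooled controls or scan day 2 alone, 1 in scan day 1 or without the low arrays, and 4 with its own set and no slide block or with the axis covariate. At day 28 (8) it was 2 with quantile normalisation, 5 with normexp, 25 with no slide block or in scan day 2, 31 with a random slide block, 950 with array weights, 4 with the authors' table, 0 with its own set alone or in scan day 1, 1 with that set and no slide block or the axis covariate, 337 with pooled controls and 47 with scan day as the block. The solvent call at day 28 (1) became 2 with no slide block, a random slide block or scan day as the block, and 0 with quantile normalisation, normexp, array weights, the authors' table, its own set alone (with or without the slide block), either scan day, without the low arrays and with the axis covariate.

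The soil count at day 4 (1349) became 750 with normexp, 2795 with array weights, 493 with its own set alone, 654 with that set and no slide block, and 20 and 158 in scan days 1 and 2. At day 14 (636) it became 974 with array weights, 165 with its own set alone, and 10 and 66 in the scan days. At day 28 (1925) it became 1033 with its own set alone, 425 and 269 in the scan days and 920 without the low arrays. The T0 count (78) became 222 with array weights, 43 with the authors' table, and 1 and 2 in the scan days. The difference of trends (4) became 148 with array weights, 166 with pooled controls, 0 in ppm, without the solvent control or in either scan day, and 7 with scan day as the block. The difference of soil changes (520) became 1193 with array weights, 0 and 4 in the scan days and 308 without the low arrays. The 101 probes shared by all sets became 57 with normexp, 184 with array weights, 0 and 4 in the scan days and 51 without the low arrays. The prediction error passed at day 14 with the authors' table (1.336), slide means removed (1.352) and a penalty 10 times smaller (1.299), and at day 28 under the same settings (1.386, 1.308 and 1.322).

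With the replicate block, the trend at day 14 gave 0 probes, each dose gave 0 at day 4 and 32 at day 28, the solvent gave 2 at day 28 and the T0 controls 34, and no other count moved by over 1.5 times. The numbers share no more than a label: deviations of same-numbered worms correlated by 0.011 on average against -0.001 for other pairs, 94 of 277 pairs lay over 0.1, the lowest was -0.599, and 19 of 119 worms correlated best with their own number.

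Leaving out 1 worm gave 0 to 1 probes for the trend at day 4, 0 to 7 at day 14 and 131 to 699 at day 28, 0 to 14, 0 to 9 and 0 to 324 for each dose, and 0, 0 and 0 to 2 for the solvent. It gave 574 to 1330, 352 to 562 and 1356 to 1786 for the soil changes, 33 to 78 for the T0 controls and 0 to 65 for the difference of trends. The difference of soil changes ran from 262 to 569 and was 262 without T0 replicate 3, 294 without blank replicate 5 and 346 without blank replicate 4 of day 4, and 308 without blank replicate 1 of day 28. The shared probes ran from 52 to 101 and were 52 without blank replicate 5 of day 4, and 55, 56 and 60 without blank replicate 9, T0 replicate 3 and T0 replicate 4 of day 14. The prediction errors were 1.492 to 1.623, 1.350 to 1.457 and 1.310 to 1.425, and passed at day 14 without 128 ppm replicate 1 (1.350) or 16 ppm replicate 1 (1.376), and at day 28 without 16 ppm replicate 3 (1.359), 32 ppm replicate 1 (1.376), 8 ppm replicate 2 (1.353) or solvent replicate 2 (1.310).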

Other observations

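All tests of this part were chosen after the results were seen. Some probes had a high level in some worms and a low one in others. Among the tested probes, 160 had a gap of over 2 log2 with at least 10 of the 120 worms on each side. TA2-058680 had its upper level, 2.6, in 43 worms and a lower one in 77, with 13, 16 and 14 upper worms of 40 in the 3 sets. TA1-097385 was at 3.81 in 109 worms and lower in 11, TA1-022210 at 0.51 in 97 and lower in 23, and TA2-057225 at 0.62 in 98 and lower in 22. Of these probes 130 lie outside the block of probes described next. Over them, the upper state held 69.7%, 70.5% and 70.3% of the arrays of the 4-day, 14-day and 28-day sets, and in the lower state a median of 9.1% of the arrays were well above background. The size of the gaps is thus not measured, and these probes were chosen by their gaps.

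A block of 500 probes, which holds the other 30 on and off probes, moved together between worms of the same group. They carry 90.5% of the leading axis of the variation left after group and slide, which holds 24.4% of it, against 5.6% for the next axis, and 494 of them were lower in worms with a high score. The mean score was -16.96 in the 4-day set, -8.25 in the 14-day set and 25.2 in the 28-day set (n = 40 each), so worms with this block low were more frequent in the 28-day set. At day 28, scores of single groups spread widely, for example from -45.23 to 105.57 in the solvent control, where the highest was that of replicate 2.

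For the block of 500 probes, slide held 8.65% of the score (permutation p = 0.763) and scan day 0.746% (p = 0.347). A share over 50% had been set as the mark of an origin in the slides. The axis was chosen after slide had been taken out, which favours a low share, so these values cannot exclude a part played by slide. Dim arrays are argued against as the whole cause, since with brightness and the detection of other dim probes as covariates the axis kept 19.6% of the variance. The exposure set held 13.7% of the score (permutation p = 0.00022, adjusted over 9 tests 0.00198), in a test over all groups, HMX groups included. In the 28-day set the mean score was 52.03, 59.7, 43 and 41.62 at 16, 32, 64 and 128 ppm (n = 5 each). It was -14.49 at 8 ppm, -9.22 in the solvent control, 4.31 in the blank control and 24.67 in T0 (n = 5 each). A difference between the worms of the sets is thus not told apart from the HMX exposure. Season or reproductive state may differ between sets, but the labels do not record them. Whether HMX moved the block at day 28 stays open, with a slope of 12.4 per doubling and a permutation p of 0.0691 (adjusted over 9 tests 0.311). A biological origin is a hypothesis, since whole worms were homogenised and a tissue present in some worms was not measured.

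The 259 probes that rose with dose at day 28 had another pattern: 215 of them had a change below 0 in unspiked soil over 28 days, where 49% of all tested probes did, and none of the 241 that could be placed on the axis belongs to the block. Scan day is argued against as the whole cause, since 191 probes passed within scan day 2 alone, although 0 did within scan day 1, from fewer worms. With the axis score as a covariate, the median change of the 282 went from 1.00 to 0.85 with an SE of 0.24 in both fits. All 282 kept their direction, but only 31 of them passed at that smaller change. The 282 were chosen by their change in the same worms, which favours a kept size and direction. Whether an uneven spread of the block over the doses accounts for the rise thus stays open. That HMX acted against the change after day 0 stays open as a candidate explanation: their mean was lower by 0.73 in the blank control than in T0 (exact permutation p = 0.0159, adjusted over 5 tests 0.0795), which misses the threshold, and the means of 1.41 at 64 ppm and 1.61 at 128 ppm lay above the 1.27 of T0. At day 14 the mean of the same probes went up by 0.19 from solvent to 128 ppm (permutation p = 0.078), so a response shared with day 14 cannot be told apart from none.

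For the 130 on and off probes outside the block, the state differed between slides for 2 probes at an unadjusted p under 0.05 and between the 24 groups for 4, where chance gives 6.5. Random spot faults are argued against for 32 of them, which had a partner in the same states (correlation over 0.9 in size), while none did in 100 shuffles. For the probes without a partner, spot faults stay open. A division of the stock into 2 lineages would put most of the 130 probes into 1 group, and the largest held 4 probes. The 30 on and off probes of the block had been left out beforehand, so this count cannot exclude 2 lineages that differ in the block. Also open is a fixed difference between worms, which may be a sequence variant under the probe or a gene that some worms lack. RNA of a passenger organism was not tested. Between the 3 exposure sets, 7 of the 130 and 24 of the 30 on and off probes inside the block differed at an unadjusted p under 0.05, and those 24 move together, so they repeat 1 difference.

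Other divisions of the same worms into groups of the same sizes were drawn 100 times, the real one included, on probes without missing values, and the shares are not adjusted over the 16 results. For the soil changes, 1 of 100, the real division itself, gave as many probes at each of days 4, 14 and 28 (real 1294, 599 and 1830, highest other 339, 129 and 728). That is the smallest share that 100 divisions can give, so chance is unlikely there but not excluded. The same holds for the T0 controls (1, real 71, highest other 10) and the trend at day 28 (1, real 260, highest other 97). The share was also 1 for the difference of soil changes (real 494, highest other 384) and the probes shared by all sets (real 99, highest other 0). For these 2 results T0 and blank worms were divided anew within each set, which removes every soil change. Such divisions cannot test whether real soil changes differed between sets or were shared by chance. The share was small for the trend at day 14 (1, real 2, highest other 1) and each dose at day 14 (3, real 6, highest other 21). These are counts of a few probes and unadjusted shares, so chance is not excluded there. For the difference of trends (2, real 3, highest other 150) the doses were divided anew within each day. This removes every trend, so a difference between days was not tested by it. Chance could not be excluded for each dose at day 28 (5, real 8, highest other 326) or the solvent at day 28 (6, real 1, highest other 14). The trend at day 4 (highest other 426), each dose at day 4 (946) and the solvent at days 4 and 14 (4 and 2) had a real count of 0, which 100 of 100 reached. For each dose at day 4 the 7 calls of the full probe set were 0 on the probes without missing values, so these divisions do not test them. Some divisions called several times the real count, as for each dose at days 14 and 28 and the difference of trends, or many probes where the real count was 0, as for the trend and each dose at day 4. Any probe was called in 38 of the other divisions for each dose at day 4, 21 for the trend at day 4, 10 and 12 for each dose at days 14 and 28, and 3 for the difference of trends. These divisions point to a structure of the worms or of their arrays whose nature was not tested.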
